A study of Mus musculus with 2 samples.

How the data were processed

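The samples were 2 cultures of mouse bone marrow cells, 1 with GM-CSF and IL-6 and 1 with GM-CSF only, grouped by the treatment in the labels. Each was hybridised to 1 Agilent array with 1 channel, Cy3, per the labels. Each array had 62976 spots, of which 59305 were not controls, and 55681 non-control probes. Of the probes, 55249 were printed once, 33 were printed 2 times and 399 were printed 10 times. Spot intensities were extracted with Agilent Feature Extraction 10.7.1.1, per the file headers, with spatial and multiplicative detrending switched on and separate background correction switched off. The deposited processed intensities were not scaled between arrays, with 75th percentiles of 486.2 with IL-6 and 549.7 without. The authors' series matrix holds log2 values of 55821 probes. Set against each array's own log2 intensities they gave r = 0.99998 on both arrays, their sorted columns differed by at most 0.00136 and both medians were 5.10, so the values are quantile-normalized log2 signals that are not centred per gene. The software of that step is not given in the sources used here.

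Log2 of the processed intensity minus its 75th percentile over non-control spots of the array was the value used. Spots marked as non-uniform or as population outliers were left out and spots of a probe averaged, which kept 55669 probes. A probe was measured on an array when at least 50% of its kept spots were well above background by the extraction software. Each gene took its probe with the highest mean level among those measured on both arrays. The log2 ratio is GM-CSF plus IL-6 minus GM-CSF only, and 2-fold (a log2 ratio of 1) was the size threshold. Printed signals are scaled to the geometric mean of the 75th percentiles of both arrays. For genes well above background on only 1 array the fold was bounded with the lowest well-above-background signal, 16.1 with IL-6 and 14.8 without. Where the dimmer signal itself was higher than this, it was used instead.

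Probes carry RefSeq and other accessions, which were named through a RefSeq table of assembly GRCm38.p6 by accession without version. Of 28109 probes with a RefSeq accession, 26577 matched 1 symbol, giving 20143 genes. A further 16179 probes are named by a genomic region and 12913 have no symbol here. No coordinates of the table were used.

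With 1 array per condition no test was possible, and the number of arrays limits the precision. The technical error is the SD of log2 ratios over spots of probes with at least 5 usable spots on both arrays (266 probes), by level, from 0.04 for bright to 0.29 for the dimmest probes. It covers spot error only, not labelling or culture. The error printed for a gene is this SD divided by the square root of its number of spots. Gene lists fixed before the data were examined are described by the median log2 ratio and its percentile among 10000 random lists of equal size matched on level in 20 bins, with ties counted at their middle. These percentiles describe this pair of arrays. Genes were named by a rule fixed before the data were examined: the 12 largest differences per direction outside the lowest 25% by level, up to 4 per list, the 5 largest bounds per direction, 5 noncoding transcripts per direction and a set of IL-6 and MDSC genes. Tubb3, Stmn2, Cpe, Chga, Nsg2, Irf7, Ccl24 and 4930528A17Rik were chosen after their values were seen.

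On data simulated from the GM-CSF only array with the measured spot error, for this comparison, 92 of 92 genes changed by 1.5 on the log2 scale and 93 of 93 changed by 2.5 that remained measured were recovered at 2-fold, with 0 of 13948 unchanged genes called. Of 400 simulated lists without a shift, 4% lay outside the central range that leaves out 5% of random lists, and 50 of 50 lists shifted by 0.2 lay outside it, over 13948 genes. The lists without a shift were drawn from the genes they were ranked against, so a share near 5% was built in. The simulation held spot error only, so it does not give the rate of false calls in these data. Real log2 ratios spread more, with an SD over the brightest genes of 0.116 against a spot SD of 0.042.

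Alternatives fixed beforehand were quantile normalization, median centring, cyclic loess, normexp with an offset of 50 on the mean and background signals, the authors' matrix, no filter or a stricter filter on dim probes, outlier spots kept, the median over a gene's probes and a looser background call. Chosen after seeing the data were marker lists for other tissues, a second interferon list, gene families by symbol, and a map of the array. For the map, the 384 rows and 164 columns of spots were divided into 336 tiles of 16 by 12 spots. A tile was called crowded when at least 4 region-named or unnamed probes in it were 2-fold apart, so that genes did not enter the choice, and 9 tiles were. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures were drawn with matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3 gave the other normalizations.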

Results

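Bone marrow cells from C57BL/6 mice were kept for 4 days in medium with 5% fetal bovine serum and 40 ng/ml GM-CSF, a growth factor of granulocytes and macrophages, with or without 40 ng/ml IL-6, an inflammatory cytokine that signals through STAT3. Cultures of this kind yield myeloid-derived suppressor cells (MDSCs), immature myeloid cells that restrain T cells. The comparison asks which mRNAs and long noncoding RNAs differ when IL-6 is added. Total RNA of each culture was labelled with Cy3 and hybridised to 1 Agilent array, so there were 2 samples and 1 array per condition. There were no replicates, so no difference has a replicate check and no p-value is given. The errors below are technical SDs from probes printed several times on an array, divided by the square root of the number of spots averaged for the gene. The plus IL-6 array had 57.9% and the GM-CSF only array 59.1% of probes well above background. No spot was saturated on either array, and both arrays shared a slide and a scan.

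The 2 cultures had closely similar profiles. Among 13843 genes measured on both arrays, 98.5% lay within 1.5-fold and the correlation of log2 levels across genes was r = 0.998, where genes are not independent replicates. A total of 39 genes were at least 2-fold higher and 14 at least 2-fold lower with IL-6, together 0.383% of those measured. Of these 53 genes, 52 lay in the lowest 25% by signal, below a scaled signal of 155.6. The exception was Tubb2b, a neuronal beta-tubulin, at 391.7 against 179.2 (log2 ratio 1.13 ± 0.08, technical SD), whose other probe gave 0.72. Among the 8049 genes brighter than the 75th percentile, log2 ratios ran from -0.73 to 0.56 with an SD of 0.13 over genes. The 2-fold counts depended on the processing, with 3 higher and 0 lower after normexp and 510 and 341 without a filter on dim probes. Crowded tiles of the array held 8 of the 14 lower and 0 of the 39 higher genes.

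**Figure D1:**
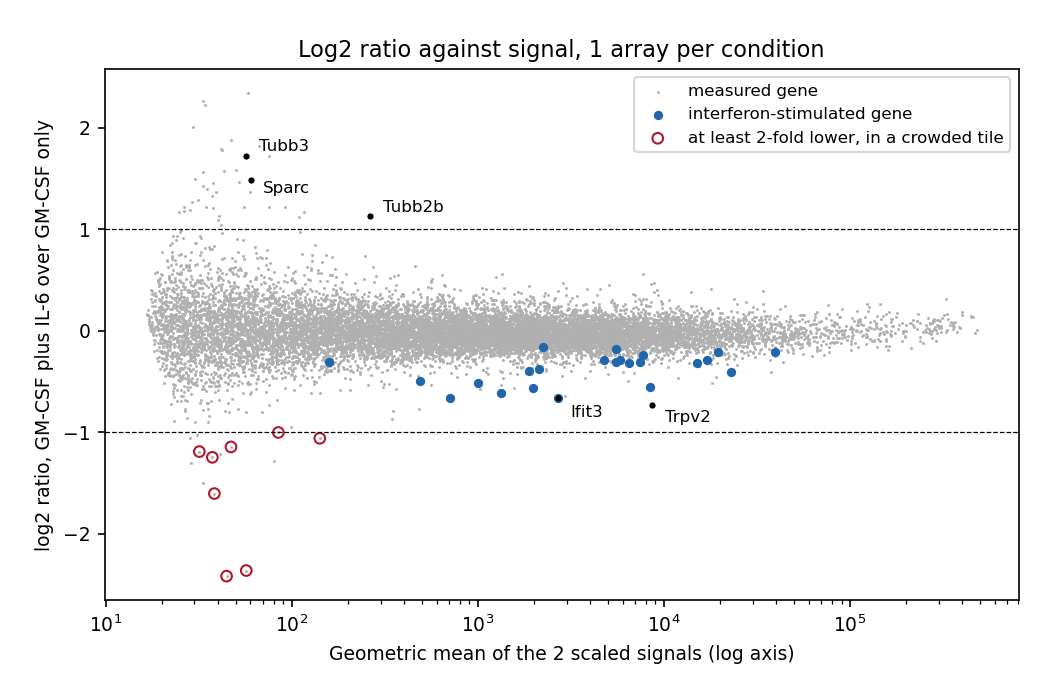
Log2 ratio of GM-CSF plus IL-6 over GM-CSF only (vertical axis) against the geometric mean of the 2 scaled signals (horizontal log axis), 1 point per gene, for 13843 genes. Blue points are the 23 interferon-stimulated genes, all below 0, red rings are genes at least 2-fold lower in crowded areas of the array, and dashed lines mark 2-fold.

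Interferon-stimulated genes were the group with the largest shared difference. All 23 measured members were lower with IL-6, with a median log2 ratio of -0.31 and a range from -0.67 to -0.16, and 0 of 10000 random lists matched on level had as low a median. Ifi44 was 1.59-fold lower (561.7 against 891.5, log2 ratio -0.67 ± 0.06) and Ifit3, which binds to viral RNA sensing complexes, was 1.58-fold lower (2145 against 3399, -0.66 ± 0.05). Ifit1, a sensor of foreign RNA caps, was 1.53-fold lower (-0.61 ± 0.06) and Rsad2, the antiviral enzyme viperin, 1.47-fold lower (-0.56 ± 0.06). Irf7, a master regulator of type I interferon genes, had a log2 ratio of -0.40 and the chemokine gene Cxcl10 -0.51. All 23 members stayed below 0 under each of the 5 other scalings and value sources. Mx1 and Mx2 were not analysed here.

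Genes known to respond to IL-6 through STAT3 lay on both sides of 0. Of 20 measured members, 8 were higher and 12 lower, with a median of -0.08 at percentile 3.43 of random lists, and below their central range in 2 other settings. Pim1, a survival kinase, was 1.29-fold higher (log2 ratio 0.37 ± 0.05), Junb 1.18-fold higher (0.24 ± 0.06) and Socs3, the feedback inhibitor of IL-6 signalling, 1.13-fold higher (0.18 ± 0.04), and the Socs3 probe lay in a crowded area of the array near its top edge. Fgl2 had a log2 ratio of -0.24, Fcgr1 -0.23 and Stat3 -0.09, with 0.06 on its other probe. The receptor genes Il6ra and Il6st had log2 ratios of -0.22 and -0.08, and Cebpb, a regulator of emergency granulopoiesis, -0.08.

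The effector genes of MDSCs differed by small amounts. Of 23 measured, 7 were higher and 16 lower, with a median of -0.07 at percentile 5.98, and in 3 other processing settings the list lay below the central range of random lists (percentiles 0.34 to 1.91). Arg1, which depletes arginine, had a log2 ratio of -0.06 ± 0.05 and Nos2, which makes nitric oxide, -0.31 ± 0.04. Cybb, the NADPH oxidase subunit, was 1.15-fold higher (0.20 ± 0.05), S100a8 and S100a9 had log2 ratios of 0.09 and 0.14, and Cd274, which encodes PD-L1, -0.15. Slc27a2 had a log2 ratio of -0.30 and Nt5e -0.30, and Ido1, a dim probe, -0.47 ± 0.29. The surface marker genes Itgam and Itgax had log2 ratios of 0.12 (-0.05 to 0.22 over 3 probes) and -0.06 and Adgre1 -0.08, with 0.02 on its other probe. Ly6g and Ly6c2 were not analysed here.

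Monocyte and mature neutrophil genes were slightly lower with IL-6 as groups. The medians were -0.11 for 15 monocyte genes (11 lower, percentile 0.665) and -0.10 for 18 mature neutrophil genes (14 lower, percentile 1.04). The median of 18 macrophage genes was -0.09 (14 lower, percentile 2.29), inside the central range of random lists in 5 of 10 other settings, and that of 20 dendritic cell genes was -0.09 (16 lower, percentile 3.01), inside that range here and below it in 2 other settings. The fractalkine receptor gene Cx3cr1 was lower (167.9 against 251.4, log2 ratio -0.58 ± 0.11, both probes -0.58). Ms4a6c had a log2 ratio of -0.43, Fpr1, a receptor for bacterial peptides, -0.36 and Apoe -0.40, while the mannose receptor gene Mrc1 had 0.27. Primary granule genes had a median of 0.01 and secondary and tertiary granule genes -0.05, inside the central range of random lists. MHC class II presentation genes had a median of 0.04, with 9 of 13 members higher (above the central range in 2 other settings), and myeloid transcription factors -0.07, among which Egr1 had 0.35 and Cebpa 0.33. Cytokine receptors had a median of -0.09 with 22 of 28 lower (percentile 0.43, and 3.17 with normexp), led by Tnfrsf1b at -0.41.

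**Figure D2:**
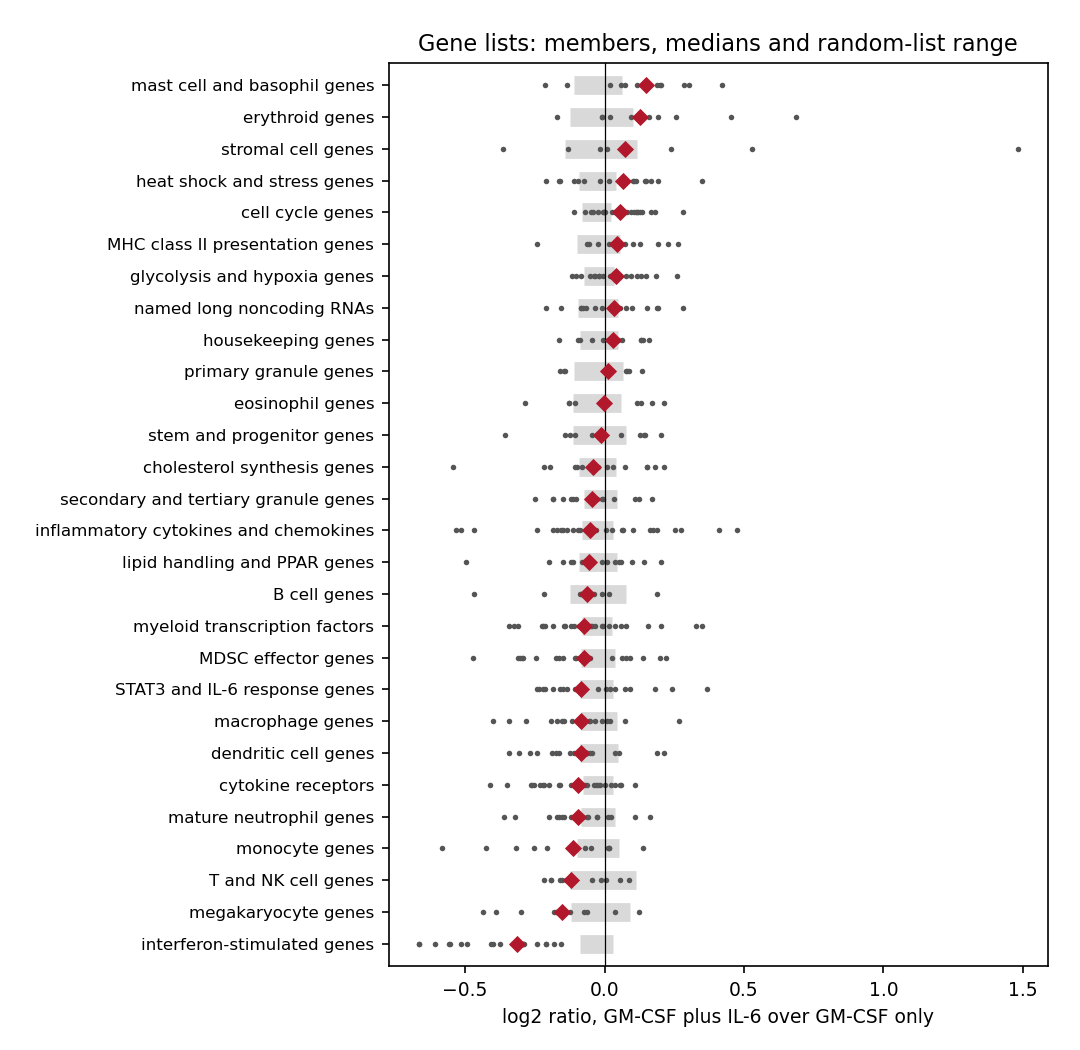
Log2 ratio of GM-CSF plus IL-6 over GM-CSF only (horizontal axis) for the measured members of 28 gene lists. Dots are genes, red diamonds list medians and grey bars the central range of medians of 10000 random lists matched on level, and the interferon-stimulated genes have the lowest median at -0.31.

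Inflammatory cytokine and chemokine genes differed in both directions, with 12 of 28 higher and a median of -0.05 (-0.01 with normexp). Tnf was 1.39-fold higher (log2 ratio 0.48 ± 0.02) and Ccl24, an eosinophil attractant, 1.33-fold higher (0.41 ± 0.06), while Ccl5 was 1.38-fold lower (-0.47 ± 0.04) and Il12a, a subunit of IL-12, had -0.53 ± 0.17. Cell cycle genes had a median of 0.06 with 19 of 28 higher (percentile 99.86), among them the replication helicase gene Mcm2 at 0.28. Glycolysis and hypoxia genes had a median of 0.04 (percentile 98.76, and 97.14 with cyclic loess), heat shock and stress genes 0.07 (percentile 99.34, and 96.89 without the crowded areas), cholesterol synthesis genes -0.04 and lipid handling genes -0.06, among which the fatty acid carrier gene Fabp4 had -0.50 ± 0.08. Housekeeping genes had a median of 0.03.

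Markers of other bone marrow cell types also differed by small amounts. Mast cell and basophil genes were higher in 11 of 13 members, with a median of 0.15 (percentile 99.98), among them the tryptase gene Tpsb2 at 0.42, whose other probe gave -0.11, and Mcpt4 at 0.30. Erythroid genes had a median of 0.13 (percentile 99.15), with the globin gene Hba-a1 at 0.69 ± 0.17. Megakaryocyte genes were lower in 9 of 11 members, with a median of -0.15 (percentile 0.485), among them Gp5 at -0.44. With normexp their median was -0.09 (percentile 1.6). T and NK cell genes had a median of -0.12 (percentile 2.56), which was -0.02 with normexp and -0.04 with the stricter filter on dim probes. The medians were -0.06 for B cell genes, -0.00 for eosinophil genes, -0.01 for stem and progenitor genes and 0.07 for stromal cell genes. Sparc, a matrix protein gene of the stromal list, was 2.79-fold higher at low signal (100.4 against 35.98, log2 ratio 1.48 ± 0.24), and it was the only 1 of 444 list members measured on both arrays that reached 2-fold. In all, 11 of 28 lists lay outside the central range that leaves out 5% of random lists, against 1.4 for independent lists without any shift.

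Outside the lowest 25% by signal, the genes with the largest log2 ratios after Tubb2b were Ifnl3 at 0.74, the histone gene H2bc8 at 0.73, Clec2d at 0.64 and Slc12a5 at 0.63, whose other probe gave 0.16. Prmt1, an arginine methyltransferase, was 1.47-fold higher (log2 ratio 0.56 ± 0.05) with 0.79 on its other probe, and Prrc2a 1.48-fold higher. Lower coding genes included Pde5a, a cyclic GMP phosphodiesterase, at -0.87 ± 0.08, Apol9b at -0.77, the channel gene Trpv2 at -0.73 and the kinase gene Sgk1 at -0.64. The Trpv2 and Sgk1 probes both lay in the outermost column of spots, where 56 bright genes had an SD of 0.17. The Pde5a and Apol9b probes lay in the first 48 rows and the Ifnl3 probe in the last 20 columns of spots, all outside the crowded tiles.

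Of the genes well above background on only 1 array, 50 were at least 2-fold higher on the plus IL-6 array and 41 on the GM-CSF only array. The dimmer signal was set to the higher of its own value and the lowest signal well above background. Such a fold is a lower bound where the signal was raised, and a plain ratio where its own value was higher, as for Slc9b1. The largest bounds with IL-6 were at least 8.40-fold for the lncRNA Gm8883, at least 7.98-fold for Sema3a and at least 7.40-fold for Gap43, genes of axon guidance and growth, and at least 7.30-fold for Dpysl3. Without IL-6 the largest folds were for Slc9b1 (192.4 against 17.98), at least 10.1-fold for Adgra2 and at least 9.39-fold for Gm7168. The genes lower with IL-6 lay close together on the array. Of the 55 genes at least 2-fold lower or seen only without IL-6, 41 (74.5%) were in 9 crowded areas near its top edge that held 2.66% of detected genes, against 1 of the 89 genes at least 2-fold higher. Slc9b1 and Adgra2 were among the 41, and Sema3a was the 1 higher gene. With these areas and the outermost spots left out, 39 genes were at least 2-fold higher and 6 lower, 3 of the 6 still in the first 48 rows or last 20 columns of spots, and 48 and 8 were seen on 1 array with a bound of at least 2-fold.

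**Figure D3:**
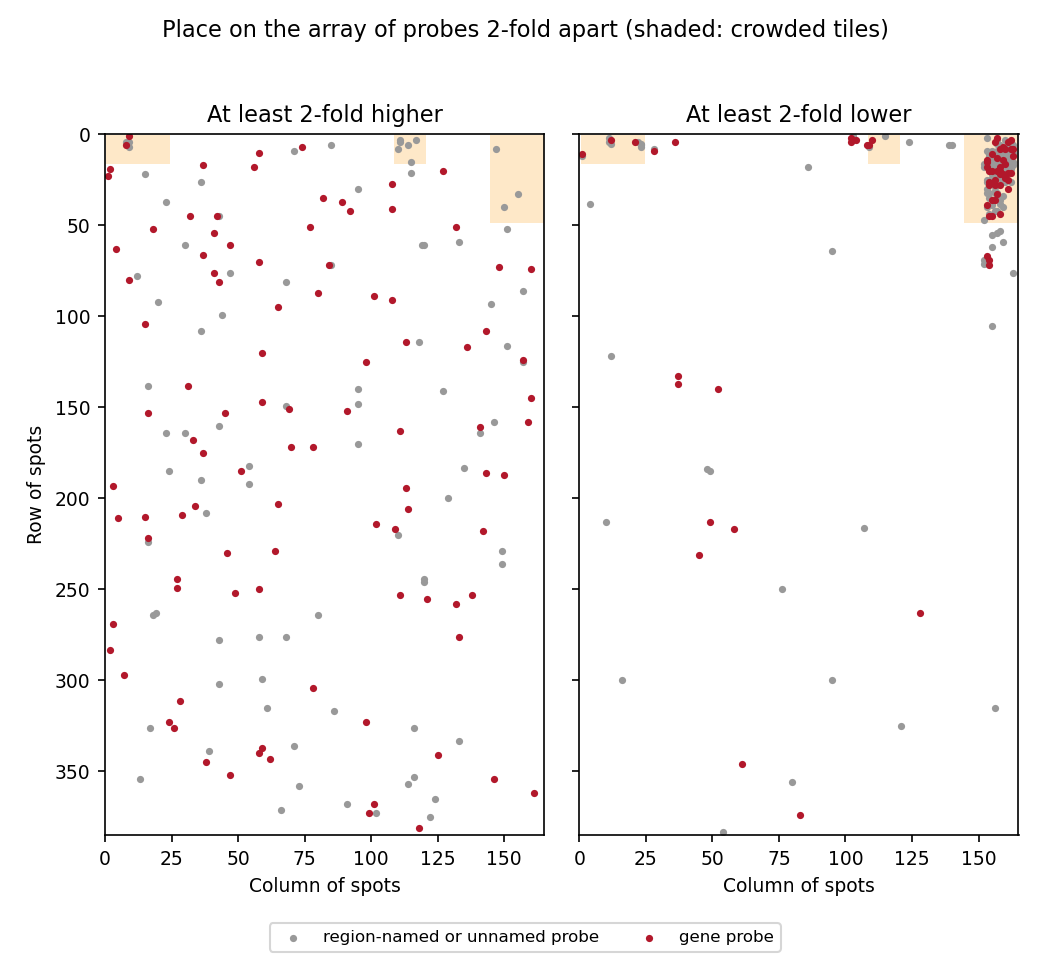
Column (horizontal axis) and row (vertical axis) of spots on the array of probes at least 2-fold higher (left) or lower (right) with IL-6, with dim signals raised to the lowest signal well above background. Red points are gene probes, grey points region-named or unnamed probes and shaded areas the 9 crowded tiles, and most lower probes lie in the upper right corner.

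Few noncoding RNAs differed by 2-fold. Of 194 measured noncoding transcripts, 1 was at least 2-fold higher, 4930528A17Rik (3.47-fold at low signal, named after its value was seen), and 0 were lower. Among the named long noncoding RNAs, 18 were measured with a median of 0.03, and Malat1 had a log2 ratio of 0.19, Ftx 0.28 and Kcnq1ot1 -0.21. Outside the lowest 25%, 1700008J07Rik had the largest log2 ratio at 0.33 ± 0.06 and 4921531C22Rik the lowest at -0.79 ± 0.08, the latter in a crowded area. Probes named only by a genomic region numbered 6898 measured, of which 29 were at least 2-fold higher and 17 lower. The count of lower ones fell to 6 with the crowded areas and outermost spots left out. Above the lowest 25% by signal, 1 was higher, at chromosome 16, 8738782 to 8830148 (2.39-fold, log2 ratio 1.26 ± 0.05, in a crowded area), and 1 lower, at chromosome X, 11690182 to 11690581 (3.17-fold, log2 ratio -1.66 ± 0.11). The genome build of these positions is not given in the sources used here.

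After normexp background correction, which lifts dim signals, 3 genes were at least 2-fold higher and 0 lower, against 39 and 14.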

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

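The 9 probes described here have no symbol in the tables used and entered no gene comparison, and the question was raised after seeing the data. They were above the lowest 25% by signal and at least 2-fold higher with IL-6 than in the GM-CSF only culture, none in a crowded area, and no such probe was 2-fold lower. The largest difference was a log2 ratio of 2.21 for probe A_55_P2126557 (1972 against 427.0), then 1.86 for the transcript ENSMUST00000099035 (4063 against 1116, technical SD 0.05). The other log2 ratios were 1.75 and 1.75, 1.71, 1.53, 1.51, 1.41 and 1.25, at scaled signals with IL-6 from 252.5 to 11057. They include 2 pairs of probes for the same transcript. Above the same signal limit, 1 gene with a symbol reached 2-fold, Tubb2b (log2 ratio 1.13). Their identity was not analysed here.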

How the results depend on the processing

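The alternative without crowded tiles and outermost spots was chosen after the results were seen and the counts of region-named probes after the files were seen, and the other choices before. The direction of no reported list outside the central random range reversed, and the interferon list kept a median between -0.33 and -0.31 under all 10 settings run on it. Quantile normalization, median centring, cyclic loess, the authors' matrix, kept outlier spots and the median over probes left every count within 1.5 times. Among recomputed list medians, 273 moved by less than 1 SD of random lists and 7 by more. Among recomputed log2 ratios of named genes, 82 moved by more than the technical SD and 1418 by less, 59 of the 82 with normexp and 16 with the median over probes, and 1 changed sign. Eosinophil, stem and progenitor and long noncoding RNA medians, near 0, changed sign in some settings. The 2-fold counts depended on signal over background and, for lower genes, on position on the array. Normexp gave 3 genes higher and 0 lower, 0 noncoding transcripts higher, and 2 region-named probes higher and 1 lower. Its list medians moved to -0.17 for monocyte genes, -0.0127 for inflammatory cytokines and chemokines, -0.0451 for myeloid transcription factors, -0.0229 for T and NK cell genes, -0.0933 for megakaryocyte genes and -0.0126 for named long noncoding RNAs, and the cause was not tested beyond its lifting of dim signals. Without a filter on dim probes 510 genes were higher and 341 lower, 17 noncoding transcripts higher and 9 lower, and 607 region-named probes higher and 525 lower. With the stricter filter, which drops the lowest 25% of genes, 1 gene was higher and 0 lower, 0 noncoding transcripts were higher, 1 region-named probe was higher and 1 lower, and the T and NK cell median was -0.0447. The looser background call gave 254 genes higher and 164 lower, with 243 and 174 seen on 1 array. Leaving out crowded tiles and outermost spots gave 6 genes and 6 region-named probes lower and 8 genes seen only without IL-6. At most 3 lists per setting crossed a limit of the central random range: macrophage genes came inside in 5 settings (percentiles 3.14 to 6.37), cytokine receptors with normexp (3.17), glycolysis genes with cyclic loess (97.14) and heat shock genes without crowded tiles (96.89). Below the range came MDSC effector genes with quantile normalization (1.875), the authors' matrix (1.91) and the median over probes (0.34), dendritic cell genes with quantile normalization (1.25) and the authors' matrix (1.28), T and NK cell genes with the median over probes (2.26), and STAT3 genes with outlier spots kept (2.08) and without crowded tiles (2.065). MHC class II genes came above it with normexp (97.56) and without crowded tiles (98.06). No paired analysis was possible because each condition had 1 array.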

Other observations

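Replication-dependent histone genes, grouped by symbol after seeing the data, were higher with IL-6 in 41 of 48 members, with a median log2 ratio of 0.17, and 0 of 10000 random lists had as high a median. The median stayed between 0.14 and 0.18 under 5 other scalings and sources. Aminoacyl-tRNA synthetase genes had a median of 0.09 (12 of 17 higher) and tubulin genes 0.12 (12 of 16 higher), with 8 and 3 of 10000 random lists as high. The tubulin genes include Tubb2b and Tubb3, already named for their size, so they are not separate support for higher neuronal transcripts. Interferon-linked families were lower, the schlafen genes in 7 of 7 members (median -0.22) and the guanylate-binding proteins in 8 of 9 (median -0.20). These families share members with the interferon lists, among them Gbp2, Gbp3 and Slfn4, so they are not separate support for that pattern. Ribosomal protein genes (0.01), proteasome subunits (-0.03), complex I subunits (-0.02), ATP synthase subunits (0.00), chaperonin subunits (0.03) and olfactory receptors (0.04) lay inside the central random range in the scaling used, and the signs of the ribosomal protein and ATP synthase medians depended on the scaling. Across 1385 bright genes with at least 2 probes, log2 ratios of the 2 brightest correlated at r = 0.466 over genes, which are not independent replicates.

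The blemish tests, with tile size and limits, were chosen after their results were seen, the tests on tissue lists, the second interferon list and plasmacytoid cells after the patterns but before their own values, and the scalings beforehand. The blemish test of the higher genes was rewritten 2 times after its result. An earlier form used the median distance of the 89 higher genes to their nearest neighbour, 10.8 spots against 13 for random sets (percentile 3.625). Tests of why the arrays differed so little were also run and not kept as weighed patterns, among them the correlation of 0.466 above and the STAT3 list percentile of 3.43, which left a failed or shared treatment open.

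The first pattern is that of genes at least 2-fold lower or seen only without IL-6. Of these 55 genes, 74.55% lay in tiles found from other probes, which held 2.66% of detected genes, and their median distance to the nearest other such gene was 2 spots against 16.6 for random sets. A candidate explanation is therefore a local blemish on an array rather than the culture. The median local background in these tiles was 51 without IL-6 and 55 with IL-6, against 52 and 51 elsewhere. Of the 14 genes outside the tiles, 7 lay in the first 48 rows or last 20 columns of spots, which held 22.0% of detected genes outside the tiles. An effect of IL-6 on these 14 genes stays open and untested.

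The second pattern is a set of transcripts known from neurons that were higher with IL-6 at low signal, such as Tubb3 (3.31-fold), Cpe (3.31-fold), Nsg2 (2.76-fold), Chga (2.68-fold) and Stmn2 (at least 6.42-fold). They were picked from the 89 higher genes, and their share of these was not counted. Other genes higher at low signal, such as Oxct2b (5.07-fold), Dsg1c (4.02-fold) and Rfesd (3.67-fold), were not picked as neuronal. A blemish in the crowded tiles is argued against, since 1.124% of the 89 higher genes lay in them. These tiles held 96 lower and 12 higher region-named or unnamed probes, so they map mostly the lower probes. A blemish elsewhere on an array stays open, and the nearest-neighbour distance of 10.8 spots against 13 (percentile 3.625) does not settle it. For a mixture of many tissues, 1 of 4 lists for liver, testis, striated muscle and epithelium had a median above the central random range (epithelium). The medians of the liver, testis and striated muscle lists were 0. Many of their members were not detected on both arrays, so these medians could hardly rise. By the mean, 0 of 4 lists lay above the range (percentiles 40.86 to 69.51), which argues only weakly against a mixture of many tissues. A list of 41 other neuronal genes lay at percentile 100 (median 0.12, a place easily reached since random medians were nearly all 0, and by the mean, added later, percentile 99.97), which is consistent with a trace of neural RNA, yet no member reached 2-fold, 4 were seen only with IL-6, 25 were measured in both cultures, the abundant Nefm and Gria2 were not well above background on either array and glial genes lay at percentile 49.78 by the mean. A response of the cultured cells to IL-6 stays open and was not tested.

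The third pattern is the lower level of interferon-stimulated genes. Scaling is argued against, since the list's median was -0.31 against -0.03 for random lists matched on level, which a scaling would shift alike. The highest percentile over 5 other scalings and sources was 0. That rank could hardly move with scaling, and the authors' matrix is itself quantile-normalized, so these are not separate checks. A chance choice of list is argued against as well, since a second list of 37 genes, 33 of them lower with a median of -0.17, lay at percentile 0. A matching drop in the number of plasmacytoid dendritic cells, which make interferon, is argued against by the median of -0.0009209 of their genes (7 higher, 7 lower, -0.14 to 0.36), against -0.31 for the first list of 23 genes (-0.67 to -0.16). The log2 ratios of the second list (-0.46 to 0.09) overlapped with those of the plasmacytoid genes. Less interferon per cell or a smaller drop with a steeper response stays open. With 1 culture per condition, an effect of IL-6 and a difference between dishes stay open and untested.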
